A study of Mus musculus with 12 samples.

How the data were processed

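RNA was measured in cells sorted from mouse epidermis as CD45+CD3-CD11b+MHCII+, per the labels' protocols. Each tube held 100 sorted cells. Wild-type (wt) and Cbfβ2 knockout (KO) mice were sampled at P5, which is day 5 after birth, and at 1.5 months of age (1.5M). The 4 groups had 3 libraries each, 12 in all, and the labels call the 3 libraries of a group separate library preparations. Whether they came from separate animals was not stated.

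Cells were lysed and their RNA fragmented by heat, and the same amount of ERCC spike-in RNA was put into every tube, per the labels' protocols. Reverse transcription used an oligo-dT primer that carries a molecular barcode, with template switching and PCR with sample indexes. A molecular barcode allows PCR copies of one molecule to be counted once. An oligo-dT primer takes molecules near their 3' end, so the values do not separate splice forms that share that end. The genome build was mm10 and the aligner TopHat2, per the submitters' processing notes. Their releases, the annotation, the counting tool, the use of strand and the way values were scaled were not given in the sources used here.

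The deposited table holds a signal per gene symbol and library that is never negative, for 23420 symbols. From the values, the authors' signal is a molecule count scaled so that every library has the same total of 37092. Within a library, 92.6% to 94.9% of the values above 0 were whole multiples, within a tolerance of 0.01, of a single step, which is what 1 molecule is worth. Most other values were fractions of that step, as when molecules that match several genes are shared between them. Genes with such fractions in several libraries, among them Cdh1, H2-D1 and Lyz2, are uncertain for that reason. Because all 12 libraries were under a limit of 95% whole values, the molecules were not treated as recovered counts and no negative binomial test was run. Approximate molecule numbers gave the depths and floors, and the chi-square comparison of replicates, the thinning and voom used them. The plan had allowed for counts or for normalized values, and the branch for normalized values was used. The spike-in RNA has no entry in the table analysed here, so no scaling by spike-in could be tried.

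The step gave each library's depth. Totals were 34192 to 52208 molecules in P5 wt, 40254 to 51848 in 1.5M wt, 30913 to 51001 in P5 KO and 74620 to 77420 in 1.5M KO. A gene with no molecule in a group could still have been present at up to 3 molecules over that group. This floor is 0.895 scaled counts in P5 wt, 0.831 in 1.5M wt, 0.907 in P5 KO and 0.485 in 1.5M KO, and it covers counting error only. Folds against a group at 0 were computed as the mean of the other group over this floor and are written as "at least". They do not allow for the spread between libraries of the other group. A fitted log2 fold change of such a gene depends on the pseudocount and is no bound. For that reason list medians were also computed with these genes at the floor, a step chosen after seeing the data. A gene at 0 in both groups then shows a change set by the 2 floors, which differ with depth. These medians are therefore no bounds either.

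Values were analysed as log2(scaled count + 1), with a pseudocount of 1. A fold change on this scale understates the change of low genes. Genes above 0 in at least 3 of the 12 libraries were tested, which left 10023 genes. One model of 4 group means over the 12 libraries was fitted with limma 3.58.1 in R 4.3.3, with a mean-variance trend and no covariate. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes of a comparison and a threshold of 0.05 with no minimum fold. There were 5 comparisons, namely KO against wt at each age, 1.5M against P5 in each genotype, and the difference between the knockout effects at the 2 ages. All adjusted p-values of genes are from this limma fit. Single values per library were compared with an exact permutation test, whose smallest possible p for 3 against 3 libraries is 0.1.

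A set of 30 gene lists, covering cell type markers, pathways and complexes, was fixed before the data were examined, together with the design, the rule for named genes and the first set of alternative settings. Lists with at least 5 tested members, 24 of the 30, were tested with limma's camera, with a preset correlation between genes of 0.01 and again with an estimated correlation. Benjamini-Hochberg adjustment ran over the 24 lists of a comparison. The fry test of limma was run on the same lists. Members past the threshold are counted over all genes tested and also "adjusted over the list alone". Gene symbols were used as the table gives them, and 4 list members were matched through an older symbol.

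The rule for named genes took, per comparison and direction, up to 8 genes with the largest fold change among those past the threshold. Their 2 groups had to show no overlap, except for the difference between knockout effects, and the higher group had to average at least 1.15, the median over tested genes. Predicted genes and pseudogenes were left out of this part. It also took up to 3 members per list and direction with the smallest adjusted p, of which the text gives some as examples, and in every comparison Cbfb, Runx1, Runx3, Cd207, Epcam, Cdh1, Tgfbr1, Tgfbr2, Itgam and Cd74. A last part, for comparisons with fewer than 5 genes past the threshold, was not needed. By chance, the groups of 10% of unchanged genes show no overlap with 3 against 3 libraries.

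Alternative settings fixed beforehand were robust variance estimation, median-of-ratios scaling, quantile normalization, no filter and a stricter filter on low genes, pseudocounts of 0.1 and 10, a replicate block, a fit to the libraries of the compared groups alone, a minimum fold, and leaving out each library in turn. Alternatives added after seeing the data were limma's voom on molecules, thinning of every library to the depth of the shallowest, scaling without the ribosomal RNA precursor Rn45s, a count without genes of other cell types, and list tests after median-of-ratios scaling or thinning.

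The gene test was tested on simulated counts that took the mean profile and the depths of these libraries. A single spread was set for all genes and groups, which is not the spread of the real libraries. In each comparison 100 genes were changed 2-fold and 100 were changed 4-fold, all drawn from the more highly counted genes. For P5 KO against P5 wt, on 9442 genes, the test recovered 11% and 36% of them, with 8 false genes among 55 calls. The corresponding shares were 1% and 27% for 1.5M KO against 1.5M wt with 0 false calls of 28 on 9442 genes. They were 5% and 37% for 1.5M wt against P5 wt with 1 false call of 43 on 9417 genes. They were 1% and 20% for 1.5M KO against P5 KO with 2 false calls of 23 on 9403 genes. For the difference between knockout effects they were 2% and 14%, with 0 false calls of 16 on 9436 genes. Most simulated changes of these sizes thus went uncalled, and the shares in the real data may differ. Positions are from the mm10 (GRCm38) annotation, in which 23009 of the 23420 symbols were placed once. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.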

Results

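Gene expression was measured in epidermal cells sorted as CD45+CD3-CD11b+MHCII+, the surface phenotype of Langerhans cells, the antigen-presenting cells of the epidermis, and of related myeloid cells. Wild-type mice (wt) and mice without Cbfβ2 (KO), a splice form of the beta subunit of the core-binding factor that partners Runx transcription factors, were compared at day 5 after birth (P5) and at 1.5 months (1.5M). Each of the 4 groups had 3 libraries of 100 cells, and p-values measure the spread between these library preparations, which may be technical. Depth was 34192 to 52208 molecules per library in P5 wt, 30913 to 51001 in P5 KO, 40254 to 51848 in 1.5M wt and 74620 to 77420 in 1.5M KO. The 1.5M KO libraries were thus deeper than the 1.5M wt libraries (exact permutation p = 0.1, the smallest that 3 against 3 allows), and they held 8065 ± 141 detected genes against 6450 ± 310 (SD, n = 3). P5 wt held 7403 ± 645 and P5 KO 7432 ± 600. All pairs of libraries of a group differed by more than sampling noise (chi-square per degree of freedom from 1.37 to 4.47). Each library was counted as 1 replicate, but this spread does not show whether they came from separate animals. Values below are scaled molecule counts, as mean ± SD over 3 libraries, and log2 fold changes are of log2(scaled count + 1) with their standard error (SE).

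Cbfb, the gene of the deleted splice form (chromosome 8, 105170674 to 105217989, mm10), was counted at low level in every library. Its scaled count was 4.97, 4.34 and 3.91 in the 3 P5 wt libraries and 3.63, 1.46 and 2.40 in the 3 P5 KO libraries. It was 13.8, 7.15 and 10.7 in 1.5M wt and 1.92, 0.99 and 2.40 in 1.5M KO. In limma's test the difference at 1.5M passed the threshold (log2 fold change −2.05, SE 0.39, adjusted p = 0.00132), and that at P5 did not (−0.67, SE 0.39, adjusted p = 0.49). A 3' tag per gene does not separate the Cbfβ2 form from others, so these values check the gene and not the form deleted. Of its partners, Runx1 averaged 3.21 ± 2.92 in P5 wt, 9.02 ± 1.54 in P5 KO, 3.92 ± 1.46 in 1.5M wt and 12.3 ± 2.78 in 1.5M KO, and Runx3 averaged 7.31 ± 2.75, 7.11 ± 2.77, 15.7 ± 5.04 and 24.7 ± 7.31 in the same order. Among the 6 tested members of the Runx/Cbf list, Cbfb fell and Runx1 rose at 1.5M (adjusted p = 0.0389), and 0 were called at P5, where 1 was higher when adjusted over the list alone. The Runx1 call was lost without 1.5M wt library 2 (adjusted p = 0.108) or 3 (0.162) and without 1.5M KO library 1 (0.164), 2 (0.0581) or 3 (0.0927), and by thinning (0.288), and the list as a whole was not called (camera adjusted p = 0.751).

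**Figure D1:**
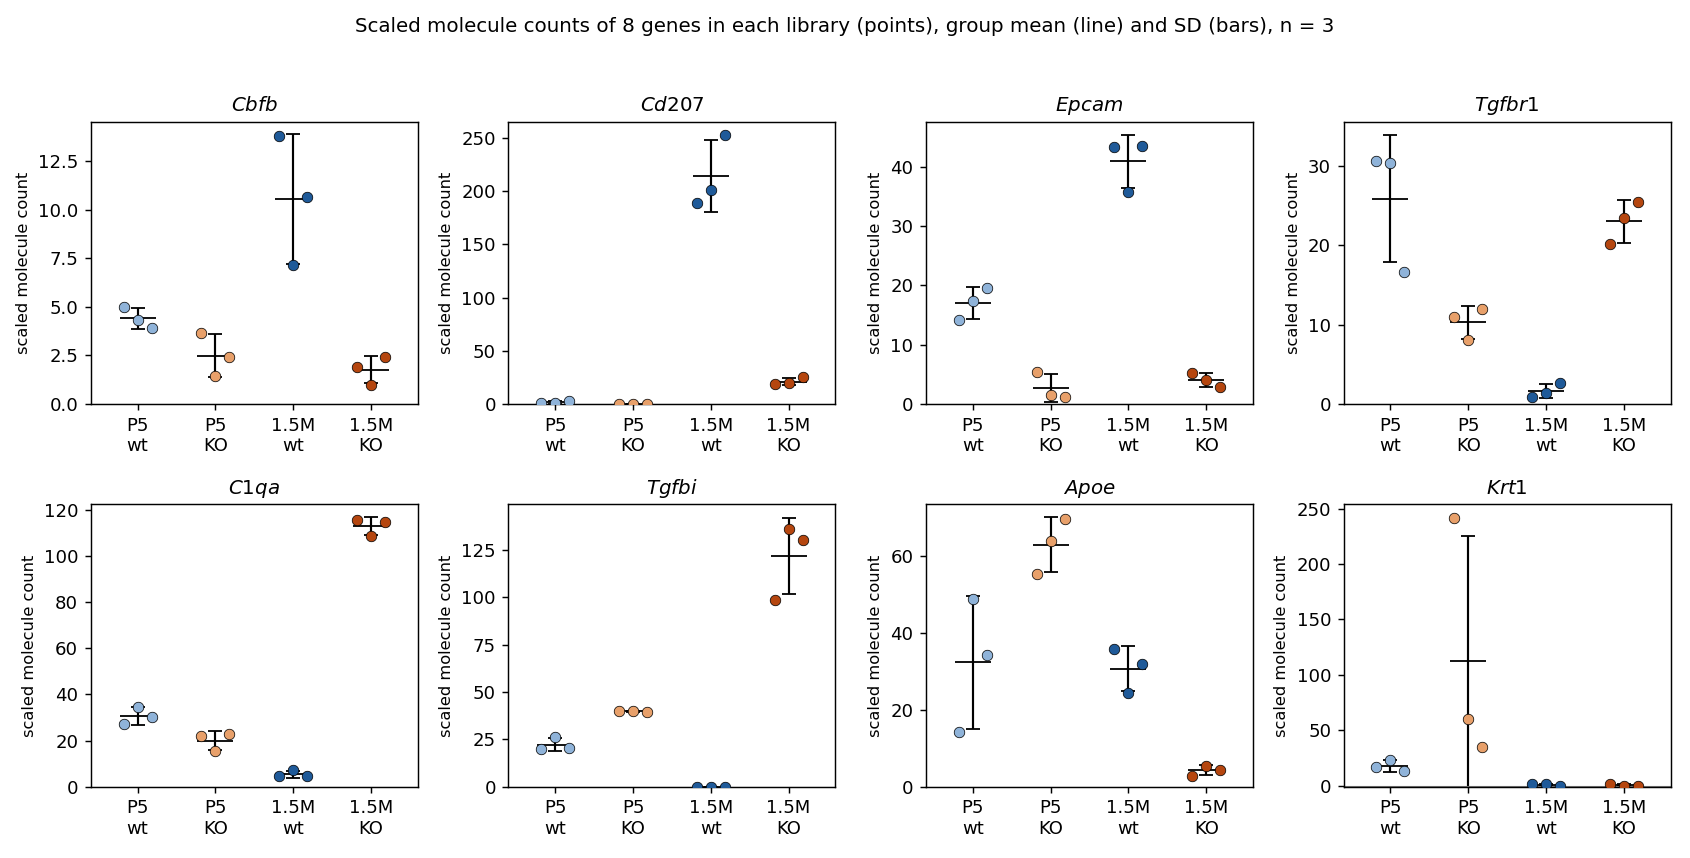
Scaled count of 8 genes in each library (vertical axis, molecules scaled to equal totals) by group, with points for libraries, a line for the group mean and bars for the SD of 3 libraries. Cd207 averaged 214 in 1.5M wt and 21 in 1.5M KO, and C1qa 5.40 and 113.

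The first 2 principal components, over 2937 genes, held 32.0% and 17.4% of the variance and kept the 4 groups apart. On the first component the 1.5M wt libraries lay between 35.5 and 37.2, and all 9 others below 0. On the second the 1.5M KO libraries lay between −28.0 and −25.2, below all others.

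**Figure D2:**
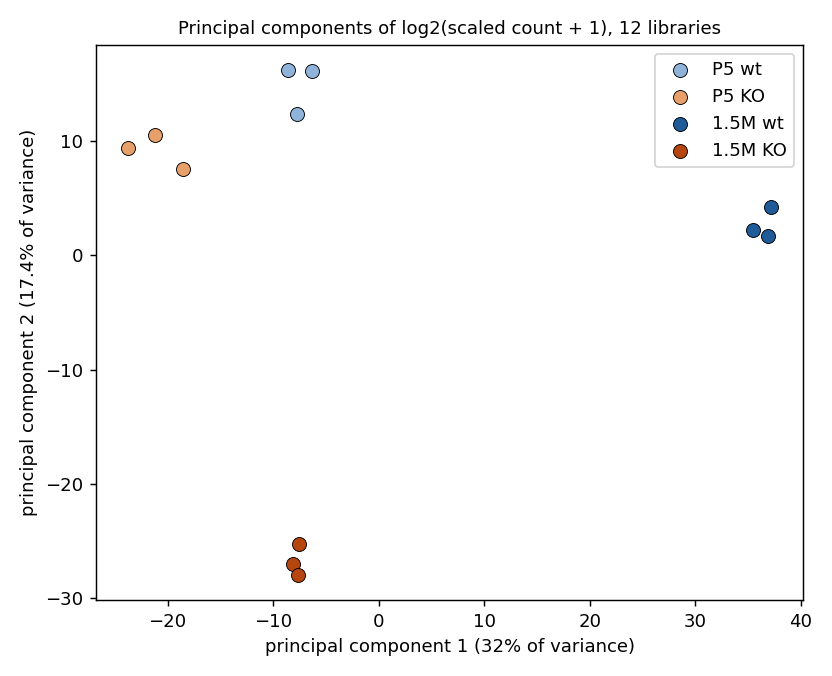
Principal components 1 and 2 of log2(scaled count + 1), which hold 32.0% and 17.4% of the variance, with a point per library coloured by group. The 3 libraries of each group sit together, and the 1.5M wt libraries lie apart from all others on component 1.

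What differs with the knockout in the sorted cells at P5 was asked by comparing P5 KO with P5 wt. All gene calls of this comparison come from the fit to all 12 libraries, and 0 passed when its 6 libraries were fitted alone. Epcam and Cdh1 were lower in P5 KO. Epcam, an epithelial cell adhesion molecule carried by Langerhans cells (chromosome 17, 87635979 to 87651129), averaged 2.70 ± 2.38 against 17.0 ± 2.68 in P5 wt, n = 3 each (log2 fold change −2.45, SE 0.35, adjusted p = 0.000489 by limma). Cdh1, which encodes E-cadherin, fell from 23.4 ± 1.47 to 4.83 ± 2.24 (−2.15, SE 0.38, adjusted p = 0.00357), a value that shares molecules with other genes in 4 libraries. Cd14, a co-receptor for bacterial lipopolysaccharide, rose from 8.12 ± 4.03 to 34.1 ± 6.08 (2.04, SE 0.31, adjusted p = 0.000812), and Dusp1, a phosphatase induced by stress, from 6.78 ± 1.23 to 34.5 ± 9.34 (2.17, SE 0.25, adjusted p = 3.28e-05). Cd207, which encodes langerin, was near the detection limit in P5 wt (0.71, 1.09 and 2.93) and 0 in all 3 P5 KO libraries. Its call (adjusted p = 0.0421) was lost without P5 wt library 2 (0.0581) or 3 (0.187) and without P5 KO library 1 (0.0915), 2 (0.0756) or 3 (0.0772), and reached 0.659 with a pseudocount of 10.

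The fixed adhesion and integrin list was not called (1 of 20 higher and 0 lower in limma, with 2 and 0 when adjusted over the list alone; camera adjusted p = 0.32). Of 11 tested members of the Langerhans cell identity list, 6 fell and 1 rose in P5 KO (adjusted over the list alone, 6 and 2). Its median log2 fold change was −1.27, or −0.54 with genes of a zero group at the detection floor (camera adjusted p = 7.01e-05, and adjusted p = 0.0205 with an estimated correlation). Ltc4s, leukotriene C4 synthase, fell from 10.5 ± 1.08 to 0.64 ± 0.60. The inflammatory cytokine and chemokine list held 8 members that rose and 1 that fell among 25 (alone, 20 and 1; camera adjusted p = 1.86e-15, and adjusted p = 0.0205 with an estimated correlation). Cxcl2, which attracts neutrophils, rose from 8.87 ± 8.36 to 59.1 ± 27.7, and Cxcl16, the ligand of Cxcr6, fell from 45.9 ± 3.6 to 14.7 ± 1.21 (adjusted p = 3.59e-05). Pattern recognition receptors had 3 members of 24 higher (alone, 5; camera adjusted p = 2.9e-05, and adjusted p = 0.0205 with an estimated correlation), among them the lectin Clec4n at 6.91 ± 2.93 against 0.69 ± 0.60. In the macrophage and monocyte list 7 of 25 members rose and 1 fell (alone, 11 and 2; median 0.70; camera adjusted p = 2.64e-06, but adjusted p = 0.0865 with an estimated correlation). In the immediate early and heat shock list 6 of 27 rose (alone, 10 higher and 1 lower; camera adjusted p = 2.64e-06, but adjusted p = 0.102 with an estimated correlation). MHC class II presentation genes had 4 of 15 members lower (alone, 4; camera adjusted p = 0.000319, but adjusted p = 0.169 with an estimated correlation). Cd74, the invariant chain, went from 753 ± 89.9 to 533 ± 58.7 (log2 fold change −0.50, adjusted p = 0.0111), a call lost without P5 wt library 2 (0.0857) or P5 KO library 1 (0.0624), by quantile normalization (0.0856) and by thinning (0.073).

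Markers of other cell types moved in the same libraries, and whether RNA of such cells also raised the inflammatory and pattern recognition genes was not tested. The neutrophil genes S100a8 and S100a9, which encode calprotectin, rose from 1.30 ± 2.26 to 52.4 ± 37.0 and from 0.47 ± 0.82 to 51.6 ± 46.6. Keratinocyte genes had 4 of 20 members higher (alone, 10; camera adjusted p = 1.05e-11, but adjusted p = 0.0685 with an estimated correlation). Neutrophil genes had 2 of 6 higher (alone, 3; camera adjusted p = 1.13e-05, but 0.0676 with an estimated correlation) and erythroid genes 3 of 5 (alone, 5; camera adjusted p = 7.21e-08, but 0.0959 with an estimated correlation). The erythroid rise rests on P5 KO libraries 1 and 2, with sums of 401 and 521 against 1.19 in library 3. Krt1, a keratin of differentiating epidermis, averaged 112 ± 113 against 17.5 ± 5.40 (adjusted p = 0.0343). The Krt1 call was lost without P5 wt library 1 (0.0952), 2 (0.0561) or 3 (0.135) and without P5 KO library 1 (0.218) or 2 (0.0646), with a pseudocount of 0.1 (0.436) and by thinning (0.148). The 3 lists together made up 3.47%, 2.25% and 1.41% of the molecules of the 3 P5 KO libraries and 0.283% to 0.350% of those of P5 wt. Y-linked transcripts summed to 4.44 in P5 KO and 0.562 in P5 wt (exact permutation p = 0.1, the smallest possible). These sums come from 3 to 7 molecules per P5 KO library and 0 or 1 per P5 wt library.

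In all, limma called 115 genes higher and 65 lower in P5 KO (180 of 10023, with 1278 at an unadjusted p under 0.05), and camera called 12 of 24 lists. The other 3 called lists were myeloid transcription factors, interferon-stimulated and cytosolic ribosomal protein genes. The first had 2 of 25 higher (alone, 3 higher and 1 lower; camera adjusted p = 0.0415, but adjusted p = 0.0959 with an estimated correlation), a call lost without P5 wt library 2 (0.197) or P5 KO library 1 (0.1) or 2 (0.0665). The interferon-stimulated list had 0 of 29 (alone, 2 higher; adjusted p = 0.044, but 0.339 with an estimated correlation), lost without P5 wt library 1 (0.0789) or 2 (0.112) or P5 KO library 1 (0.258) or 2 (0.0614). The ribosomal list had 0 of 47 called, with a median of −0.25 (adjusted p = 4.67e-06, but 0.201 with an estimated correlation). The count of genes fell to 0 when the 6 libraries of this comparison were fitted alone in limma (836 at an unadjusted p under 0.05), to 80 or 72 without P5 wt library 2 or 3, and to 88, 107 or 116 without P5 KO library 1, 2 or 3. It was 92 with a pseudocount of 0.1, 118 with no filter on low genes, 118 after thinning, and 163 without keratinocyte, neutrophil and erythroid genes and their families. Median-of-ratios scaling gave 111 higher and 40 lower, and leaving out P5 wt library 3 gave 37 and 35.

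At 1.5M the same comparison of KO with wt gave differences in markers of Langerhans cells and of macrophages. Cd207 (chromosome 6, 83671215 to 83677857) averaged 21 ± 3.41 in 1.5M KO against 214 ± 33.7 in 1.5M wt, n = 3 each (log2 fold change −3.29, SE 0.32, adjusted p = 1.75e-07). Epcam fell from 40.9 ± 4.42 to 4.04 ± 1.2 (−3.08, SE 0.35, adjusted p = 2.88e-06), and Cldn1, a tight junction claudin of Langerhans cells, from 56.8 ± 0.82 to 0.32 ± 0.28. The complement genes C1qa, C1qb and C1qc, products of tissue macrophages, rose, with C1qa (chromosome 4, 136895917 to 136898803) at 113 ± 3.72 against 5.40 ± 1.52 (4.18, SE 0.23, adjusted p = 1.63e-11). Tgfbi, a matrix protein induced by TGF-β (chromosome 13, 56609523 to 56639562), averaged 122 ± 20.1 in 1.5M KO and was 0 in 1.5M wt, at least 146-fold higher. Cybb, the catalytic subunit of the phagocyte NADPH oxidase, was at least 66.9-fold higher.

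The Langerhans cell identity list had 7 of 11 members lower and 1 higher (alone, the same counts; median −2.86; camera adjusted p = 9.43e-14, and adjusted p = 0.000971 with an estimated correlation). Cdh1 fell too, from 30.6 ± 4.16 to 9.47 ± 6.45 (adjusted p = 0.00383, but 0.122 in a fit of the 6 libraries alone). The macrophage and monocyte list had 13 of 25 members higher and 1 lower (alone, 21 and 1; median 2.23, or 1.96 with zero groups at the floor; camera adjusted p = 2.04e-26, and adjusted p = 0.00304 with an estimated correlation). The exception was Apoe, which encodes a lipid carrier and fell from 30.8 ± 5.91 to 4.22 ± 1.30 (−2.62, SE 0.32, adjusted p = 6.46e-06). In the TGF-β and BMP list 7 of 24 rose (alone, 10; median 0.63, or 0.44 with zero groups at the floor; camera adjusted p = 6.04e-06, and adjusted p = 0.0143 with an estimated correlation). Tgfbr1, the type I receptor for TGF-β (chromosome 4, 47353222 to 47414931), was 23 ± 2.65 in 1.5M KO and 1.67 ± 0.90 in 1.5M wt (3.21, SE 0.31, adjusted p = 2.33e-07). Tgfbr2 rose from 3.55 ± 0.82 to 14.6 ± 3.98 (adjusted p = 0.0203), a call lost without 1.5M wt library 1 (0.0508) or 3 (0.0891) and without 1.5M KO library 1 (0.0538) or 2 (0.109).

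Lysosomal genes had 9 of 27 members higher (alone, 13; camera adjusted p = 1.37e-09, and adjusted p = 0.00319 with an estimated correlation), such as Psap, which encodes prosaposin, at 78.4 ± 9.81 against 20.9 ± 3.82, and the protease gene Ctsb at 45.9 ± 2.19 against 19.4 ± 2.83. Pattern recognition receptors had 5 of 24 higher (alone, 9; median 0.92, or 0.22 with zero groups at the floor; camera adjusted p = 2.3e-05, and adjusted p = 0.00576 with an estimated correlation), with Cd14 at 60.9 ± 10.4 against 1.98 ± 0.63. Myeloid transcription factors had 6 of 25 higher (alone, 9; camera adjusted p = 0.00261, and adjusted p = 0.0248 with an estimated correlation), among them Cebpa and Zeb2, regulators of monocyte and dendritic cell fate. Adhesion genes and integrins had 4 of 20 higher (alone, 7 higher and 2 lower; camera adjusted p = 0.00576, and adjusted p = 0.0485 with an estimated correlation), with the tetraspanin Cd81 at least 26.3-fold higher.

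MHC class II presentation genes went both ways, with 5 of 15 lower and 2 higher (alone, 6 and 2; camera adjusted p = 0.000679, but adjusted p = 0.184 with an estimated correlation). The class II chains H2-Eb1 and H2-Ab1 fell, H2-Eb1 from 689 ± 46.1 to 335 ± 29.0 (−1.04, SE 0.13, adjusted p = 1.15e-05), while the protease gene Lgmn rose from 1.67 ± 0.90 to 34.3 ± 4.62. Cd74 went from 1614 ± 95.2 to 1049 ± 146 (adjusted p = 0.000224), a call lost by quantile normalization (0.452) and in a fit of the 6 libraries alone (0.143). The MHC class I genes B2m and H2-D1 rose, the latter with fractional values, and the class I list was not called (camera adjusted p = 0.623; 2 of 17 higher, and 2 when adjusted over the list alone). Inflammatory genes had 4 of 25 higher (alone, 4; camera adjusted p = 0.00307, but adjusted p = 0.283 with an estimated correlation). Among dendritic cell activation genes, 3 of 20 rose and 1 fell (alone, 3 and 1; camera adjusted p = 0.148), and the chemokine gene Ccl17 averaged 27.0 ± 18.6 against 0.24 ± 0.41 (adjusted p = 3.46e-06). Dermal dendritic cell markers had 2 of 12 members higher and 2 lower (alone, 2 and 2; adjusted p = 0.591), keratinocyte genes 0 of 20 (alone, 0; adjusted p = 0.267).

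Limma called 325 genes higher and 204 lower in 1.5M KO (529, with 1492 at an unadjusted p under 0.05), and camera 14 of 24 lists. The 5 called lists not yet given were lost with an estimated correlation. Cholesterol synthesis genes had 1 of 24 lower (alone, 1; adjusted p = 0.00576, but 0.0698 with an estimated correlation), cell cycle genes 2 of 37 higher (alone, 2; 0.0104, but 0.386 with an estimated correlation) and ribosomal protein genes 0 of 47 (alone, 0; 0.000136, but 0.283 with an estimated correlation). Immediate early and heat shock genes had 3 of 27 higher and 4 lower (alone, 4 and 5; adjusted p = 0.0321, but 0.386 with an estimated correlation), a call lost without 1.5M wt library 2 (0.0792) or 1.5M KO library 3 (0.0721). Interferon-stimulated genes had 2 of 29 higher (alone, 3; adjusted p = 0.0367, but 0.325 with an estimated correlation), lost without 1.5M wt library 1 (0.111) or 3 (0.0641) or 1.5M KO library 1 (0.225), and their median of 0.38 turned to −0.12 with zero groups at the floor. The floors of the 2 groups differ with depth, and the erythroid median likewise went from 0 to −0.30, all 5 members having a zero group. The turn of the interferon median is therefore no evidence of a fall. The count of genes was 348 after thinning all libraries to equal depth and 865 by voom. Y-linked transcripts summed to 1.18 in 1.5M KO and 3.70 in 1.5M wt (exact permutation p = 0.1, the smallest possible). These sums come from 2 to 3.33 molecules per 1.5M KO library and 3 to 6.7 per 1.5M wt library.

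The change with age in wild type was taken from 1.5M wt against P5 wt. Cd207 rose from 1.58 ± 1.19 to 214 ± 33.7 (log2 fold change 6.47, SE 0.32, adjusted p = 7.12e-12, n = 3 each). Il1r2, the interleukin-1 decoy receptor, rose from 5.58 ± 1.77 to 133 ± 15.4 (4.38, SE 0.31, adjusted p = 3.51e-09), and Tbc1d4, a Rab GTPase-activating protein, from 6.87 ± 1.73 to 111 ± 13. Fosb, an immediate early transcription factor, rose from 15.1 ± 8.11 to 132 ± 27.5 (3.14, SE 0.27, adjusted p = 7.44e-08). C1qa fell from 30.7 ± 3.87 to 5.40 ± 1.52 (−2.33, SE 0.23, adjusted p = 4.7e-07), and Tgfbi fell from 22.2 ± 3.38 to 0, at least 26.6-fold lower. Tgfbr1 fell from 25.8 ± 8 to 1.67 ± 0.90 (−3.33, SE 0.31, adjusted p = 2.23e-07).

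The Langerhans cell identity list had 5 of 11 members higher and 1 lower (alone, 6 and 1; median 1.03; camera adjusted p = 1.41e-07, and adjusted p = 0.0091 with an estimated correlation). The lower member was Id2, an inhibitor of DNA binding, whose call was lost in a fit of the 6 libraries alone (0.166) and by thinning (0.0627). Mfge8, a secreted adaptor for apoptotic cells, rose from 5.56 ± 2.70 to 70.1 ± 7.07. Epcam also rose (adjusted p = 0.0461), but without P5 wt library 1, 2 or 3 that value was 0.151, 0.0948 or 0.0715, and without 1.5M wt library 1, 2 or 3 it was 0.127, 0.0816 or 0.136. Immediate early and heat shock genes had 12 of 27 higher (alone, 14; median 1.09; camera adjusted p = 2.6e-17, and adjusted p = 0.019 with an estimated correlation). Lysosomal genes had 7 of 27 lower (alone, 11; camera adjusted p = 7.47e-06, and adjusted p = 0.019 with an estimated correlation). In the macrophage and monocyte list 10 of 25 fell (alone, 11; median −0.94, or −0.66 with zero groups at the floor; camera adjusted p = 2.1e-08, but adjusted p = 0.0544 with an estimated correlation). MHC class II genes had 6 of 15 higher and 2 lower (alone, 6 and 2; camera adjusted p = 1.43e-06, but adjusted p = 0.108 with an estimated correlation). H2-Aa, a class II alpha chain (chromosome 17, 34282744 to 34287823), rose from 456 ± 40.2 to 1089 ± 109 (1.25, SE 0.10, adjusted p = 2.94e-08). TGF-β and BMP genes had 3 of 24 higher and 3 lower (alone, 3 and 5; camera adjusted p = 0.362).

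Keratinocyte genes had 5 of 20 lower at 1.5M (alone, 9; camera adjusted p = 1.22e-05, but adjusted p = 0.229 with an estimated correlation), Krt1 going from 17.5 ± 5.40 to 0.66 ± 0.58. Cell cycle genes had 1 of 37 lower (alone, 11; camera adjusted p = 9.96e-05, but adjusted p = 0.266 with an estimated correlation). Their only called member, Cdc20, was lost without 1.5M wt library 1 (0.0615), 2 (0.0608) or 3 (0.0601). Inflammatory genes had 6 of 25 higher and 1 lower (alone, 7 and 4; camera adjusted p = 0.0075, but 0.297 with an estimated correlation), with a median of −0.02 (0.29 with zero groups at the floor), a mean of 0.22 and a test pointing up, a call lost without P5 wt library 3 (0.06). Dendritic cell activation genes had 2 of 20 higher and 1 lower (alone, 5 and 3; adjusted p = 0.0126, but 0.229 with an estimated correlation), lost without P5 wt library 1 (0.0839), and Cd83, a marker of mature dendritic cells, rose from 7.58 ± 1.87 to 72.0 ± 18.6. Oxidative phosphorylation genes had 2 of 38 lower (alone, 1 higher and 4 lower; adjusted p = 0.0338, but 0.297 with an estimated correlation), lost without P5 wt library 1 (0.0523) or 2 (0.114) or 1.5M wt library 2 (0.106) and by median-of-ratios scaling (0.333). Ribosomal protein genes had 3 of 47 lower (alone, 3; adjusted p = 0.000902, but 0.325 with an estimated correlation), and median-of-ratios scaling gave 0.92.

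Limma called 237 genes higher and 285 lower with age in wild type (522, with 1821 at an unadjusted p under 0.05), and camera 11 of 24 lists. Median-of-ratios scaling moved the median of all genes from −0.22 to −0.11 and gave 286 higher and 183 lower, and quantile normalization moved it to −0.06 with 277 and 226. The count was 111 when the 6 libraries were fitted alone, 305 after thinning, and 346 or 347 without 1.5M wt library 1 or 2. The sum of Y-linked transcripts was 3.70 in 1.5M wt against 0.562 in P5 wt (exact permutation p = 0.1, the smallest possible). These sums come from 3 to 6.7 molecules per 1.5M wt library and 0 or 1 per P5 wt library.

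Whether knockout cells change with age was asked in 1.5M KO against P5 KO. Cd207 rose from 0 to 21 ± 3.41, at least 23.2-fold (adjusted p = 1.58e-08, n = 3 each). Mmp12, the macrophage elastase, rose from 0.61 ± 1.05 to 37.3 ± 17.3 (log2 fold change 4.67, SE 0.48, adjusted p = 1.64e-06), and Ccl17 from 0 to 27.0 ± 18.6, at least 29.8-fold. C1qa rose from 19.96 ± 4.09 to 113 ± 3.72 (2.47, SE 0.23, adjusted p = 5.89e-07), whereas Apoe fell from 63.0 ± 7.15 to 4.22 ± 1.30 (−3.64, SE 0.32, adjusted p = 3.84e-07). S100a8, a neutrophil gene, fell from 52.4 ± 37.0 to 0, at least 108-fold from the P5 KO mean.

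Genes of other cell types fell as groups. Keratinocyte genes had 15 of 20 members lower (alone, 18; median −2.65; camera adjusted p = 1.48e-27, and adjusted p = 0.0295 with an estimated correlation), neutrophil genes 2 of 6 (alone, 5; median −1.70; camera adjusted p = 1.58e-07, and adjusted p = 0.0354 with an estimated correlation). Erythroid genes had 5 of 5 lower (alone, 5; camera adjusted p = 1.58e-07, but adjusted p = 0.107 with an estimated correlation) and fibroblast genes 0 of 5 (alone, 3 lower; 0.00496, but 0.161 with an estimated correlation). The erythroid fall rests on P5 KO libraries 1 and 2, since the erythroid sum was 401, 521 and 1.19 in P5 KO libraries 1, 2 and 3. These 3 lists of keratinocyte, neutrophil and erythroid genes took 1.41% to 3.47% of the molecules in P5 KO and at most 0.0911% in 1.5M KO. TGF-β and BMP genes had 5 of 24 higher (alone, 7; median 0.59, or 0.53 with zero groups at the floor; camera adjusted p = 1.58e-05, and adjusted p = 0.0354 with an estimated correlation), among them Smad7, an inhibitor of TGF-β signalling, at 11.9 ± 4.05 against 1.73 ± 0.50. Tgfbr2 rose as well (adjusted p = 0.0166), a call lost without P5 KO library 2 (0.0906) or 1.5M KO library 2 (0.0923). Runx3 rose from 7.11 ± 2.77 to 24.7 ± 7.31 (1.68, SE 0.34, adjusted p = 0.00478), a call lost after thinning (0.0759) and in a fit of the 6 libraries alone (0.0765).

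MHC class II genes had 6 of 15 higher (alone, 6; camera adjusted p = 4.25e-08, but adjusted p = 0.0582 with an estimated correlation), H2-Aa rising from 333 ± 44.8 to 700 ± 49.5. The Langerhans cell identity list was not called (camera adjusted p = 0.632), with 2 of 11 higher and 3 lower (alone, 2 and 4). The macrophage and monocyte list had 7 of 25 higher and 2 lower (alone, 9 and 6; adjusted p = 0.00154, but 0.224 with an estimated correlation), and dendritic cell activation genes 3 of 20 higher (alone, 5; 0.000119, but 0.0628 with an estimated correlation). Adhesion genes had 4 of 20 higher (alone, 5 higher and 1 lower; adjusted p = 0.00496, but 0.0582 with an estimated correlation), lost without P5 KO library 2 (0.0633), with the integrin gene Itgax rising from 5.14 ± 2.63 to 34.3 ± 4.48. Immediate early genes had 4 of 27 higher and 2 lower (alone, 8 and 2; adjusted p = 0.0083, but 0.355 with an estimated correlation), lost without P5 KO library 2 (0.0673). Ribosomal protein genes had 1 of 47 lower (alone, 4; adjusted p = 0.000344, but 0.355 with an estimated correlation), lost without P5 KO library 2 (0.153) and by median-of-ratios scaling (0.074). Limma called 172 genes higher and 143 lower (315, with 1426 at an unadjusted p under 0.05), and camera 11 of 24 lists. The count was 86 when the 6 libraries were fitted alone, 190 after thinning, 910 by voom (248 higher and 662 lower), 200 without P5 KO library 1, and 184, 169 or 180 without 1.5M KO library 1, 2 or 3. Lists called fell to 7 without P5 KO library 2.

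**Figure D3:**
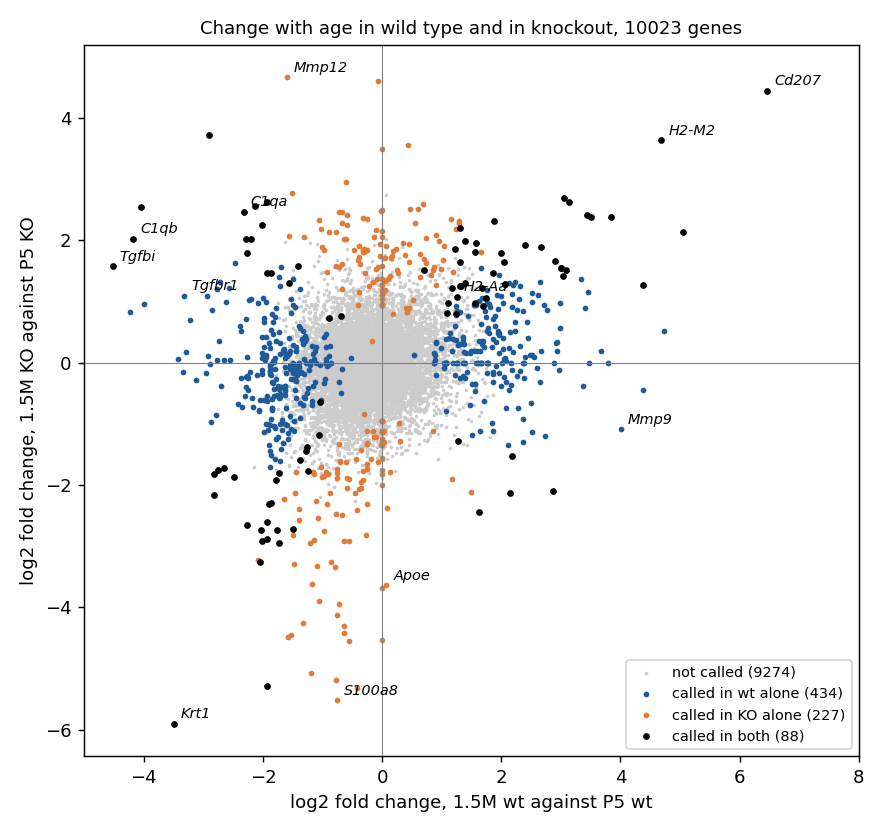
Log2 fold change of 10023 genes from P5 to 1.5M in wild type (horizontal axis) and in knockout (vertical axis), coloured by whether limma called the gene in both (88), in wild type alone (434) or in knockout alone (227). Cd207 rose in both genotypes, whereas C1qa, C1qb and Tgfbi fell in wild type and rose in knockout.

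Set side by side, the age changes of the 2 genotypes, which share no library, correlated weakly across genes (Pearson r = 0.186, covariance 0.0926; genes are not independent replicates). Of the genes higher with age in wild type, 40 were also higher with age in KO (4.07 for independent lists), and of the lower ones 26 were also lower (4.07). A further 17 genes fell in wild type and rose in KO (4.89 for independent lists), and 5 rose in wild type and fell in KO (3.38), namely Btg1, Cd24a, Cldn1, Nedd4 and Ptgs1. At the 2 ages the knockout effects shared 31 higher genes (3.73 for independent lists) and 25 lower genes (1.32), with r = 0.142 across genes. Another 1 gene, Btg1, was higher in KO at P5 and lower at 1.5M (2.34), and 4 were lower at P5 and higher at 1.5M (2.11), namely B2m, Tgfbr1, Vim and Zmynd15. These genes are listed for their calls, after their values were seen. The values for independent lists take all 10023 genes as equally likely to be called. Low genes are called less easily, so these values are too low by an amount that was not tested. Of the 237 genes higher with age in wild type, 124 were lower in 1.5M KO than in 1.5M wt (4.82 for independent lists), and of the 285 lower ones 110 were higher (9.24). These counts use the same 1.5M wt libraries on both sides, and part of the excess may come from that. In 100 simulated draws with no effect the covariance averaged −0.103, against −0.330 observed (r −0.499 and −0.604). The highest simulated overlap was 0, but with no effect almost no gene is called, so it does not show how much of the counts comes from the shared libraries.

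The test of whether the knockout effect differed between ages called complement and TGF-β genes. C1qa was 19.96 ± 4.09 in P5 KO and 30.7 ± 3.87 in P5 wt, but 113 ± 3.72 in 1.5M KO and 5.40 ± 1.52 in 1.5M wt (difference of log2 fold changes 4.79, SE 0.32, adjusted p = 3.07e-09). Tgfbr1 fell at P5 and rose at 1.5M (difference 4.43, SE 0.45, adjusted p = 1.81e-06). Its call at P5 (adjusted p = 0.0487) was lost without P5 wt library 1 (0.165) or 2 (0.185) and without P5 KO library 1 (0.114), 2 (0.151) or 3 (0.0753), and with a replicate block (0.0691). Zmynd15 fell at P5 from 18.5 ± 2.17 to 1.67 ± 1.08 and rose at 1.5M from 2.20 ± 2.22 to 32.6 ± 3.67 (difference 6.63, SE 0.63, adjusted p = 6.97e-07), the call at P5 being lost with a pseudocount of 0.1 (0.101). The P5 calls of Tgfbr1 and Zmynd15 were also lost in a fit of the 6 P5 libraries alone, which called 0 genes. Apoe had a lower effect at 1.5M, going from 32.4 ± 17.4 to 63.0 ± 7.15 at P5 and from 30.8 ± 5.91 to 4.22 ± 1.30 at 1.5M (difference −3.71, SE 0.45, adjusted p = 2.59e-05). Its rise at P5 did not pass the threshold in limma.

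The macrophage and monocyte list had 9 of 25 members with a higher effect at 1.5M and 1 with a lower (alone, 14 and 1; median 1.41, or 0.87 with zero groups at the floor; camera adjusted p = 9.03e-10, and adjusted p = 0.0341 with an estimated correlation). Lysosomal genes had 4 of 27 higher (alone, 11; camera adjusted p = 1.9e-06, and adjusted p = 0.0206 with an estimated correlation), TGF-β and BMP genes 5 of 24 (alone, 6; 8.92e-05, and adjusted p = 0.0341 with an estimated correlation). The Langerhans cell identity list had 3 of 11 lower and 1 higher (alone, 5 and 1; camera adjusted p = 1.42e-05, and adjusted p = 0.0206 with an estimated correlation). Neutrophil genes had 3 of 6 lower (alone, 4; 7.63e-07, and adjusted p = 0.0341 with an estimated correlation). Keratinocyte genes had 0 of 20 (alone, 8 lower; 1.33e-08, but 0.0993 with an estimated correlation) and erythroid genes 0 of 5 (alone, 5 lower; 2.07e-05, but 0.191 with an estimated correlation). Immediate early genes had 1 of 27 lower (alone, 10; 5e-08, but 0.0825 with an estimated correlation) and inflammatory genes 1 of 25 each way (alone, 2 higher and 4 lower; 0.00108, but 0.229 with an estimated correlation). Cell cycle genes had 0 of 37 called in limma (alone, 0; camera adjusted p = 0.0472, but 0.478 with an estimated correlation). That list call was lost without P5 wt library 1 (0.16), P5 KO library 3 (0.629), 1.5M wt library 2 (0.127) or 3 (0.0771), and 1.5M KO library 1 (0.0893) or 3 (0.112). Limma called 132 genes with a higher and 68 with a lower effect at 1.5M (200, with 1332 at an unadjusted p under 0.05), and the count was 133 with a pseudocount of 0.1, 105 after thinning and 348 by voom.

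**Figure D4:**
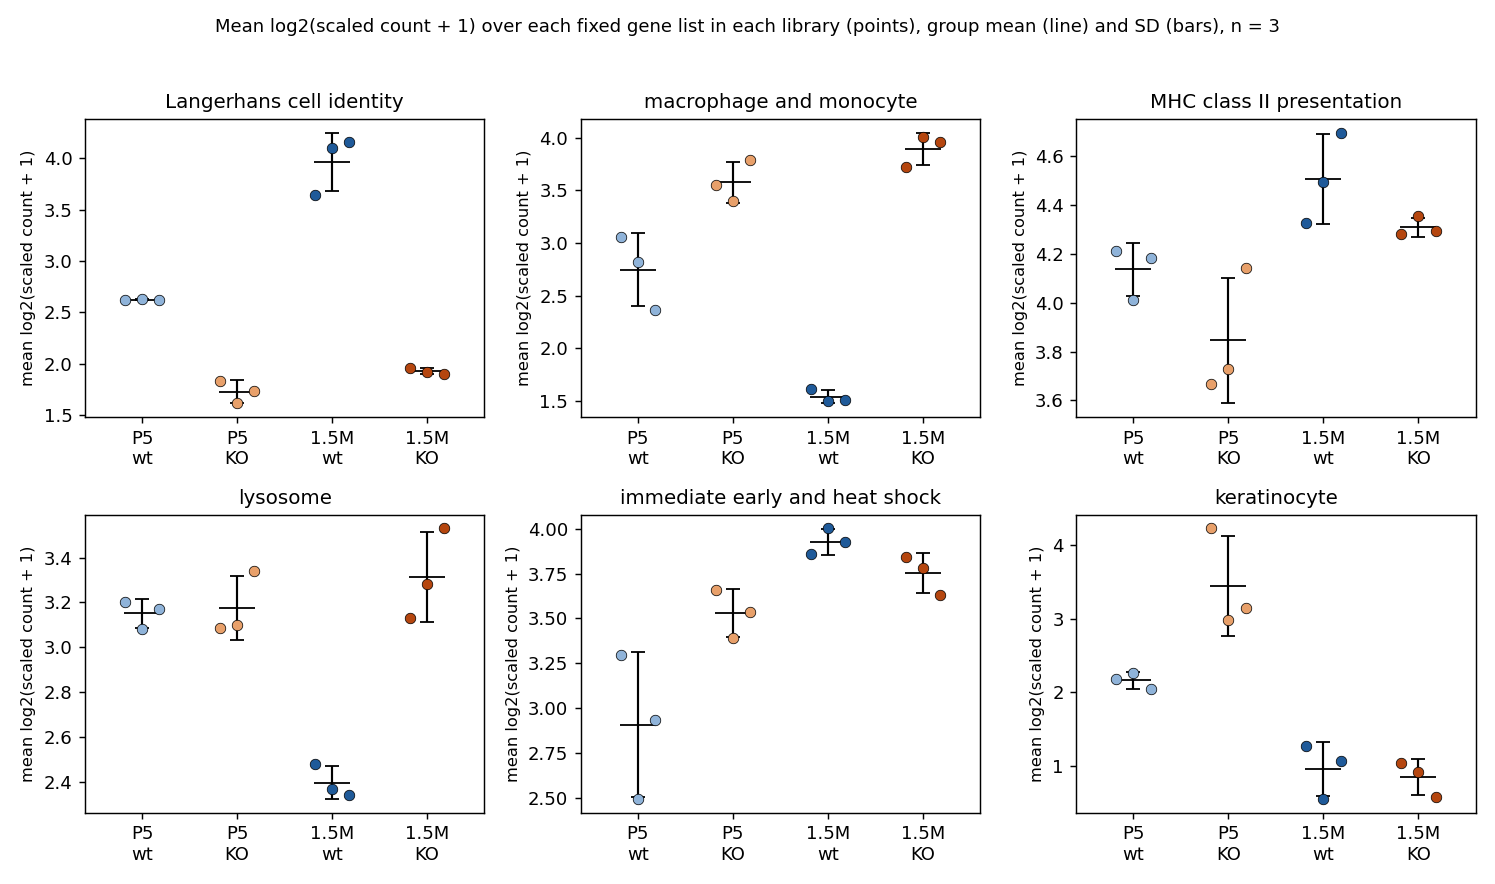
Mean log2(scaled count + 1) over the members of gene lists (vertical axis) in each library by group, with a point per library, a line for the group mean and bars for the SD of 3 libraries. By group mean, macrophage and monocyte genes stand highest in 1.5M KO and Langerhans cell identity genes in 1.5M wt. For macrophage and monocyte genes, P5 KO library 3 (3.787) lies above 1.5M KO library 1 (3.717).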

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

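All weighing tests given here were chosen after the result was seen, except the splits of the libraries and the number of genes detected after thinning.

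The knockout effect differed between the ages for 200 genes by the test of the difference itself, and each value that follows is such a difference of log2 fold changes, 1.5M minus P5. It was 6.63 for Zmynd15, 6.6 for C1qc, 6.27 for Mmp12, 6.20 for C1qb, 6.10 for Tgfbi, 5.06 for Tmem119, 4.96 for Cybb, 4.79 for C1qa and 4.43 for Tgfbr1. It was −5.09 for Mmp9, a gelatinase, −4.97 for Nedd4, −4.89 for S100a9, −4.82 for Prnp, −4.76 for S100a8, −4.53 for Retnla, −4.28 for Cd24a, −4.22 for P2ry10 and −2.02 for Cd207. The Cd207 call was lost without 1.5M wt library 3 (adjusted p = 0.0677), and with a pseudocount of 0.1 its value turned to 0.49 (adjusted p = 0.823). List medians were 1.41 for macrophage and monocyte, 0.74 for lysosome, 0.72 for TGF-β and BMP, and 0.64 for cell cycle genes. They were −0.61 for inflammatory, −0.65 for immediate early and heat shock, −1.05 for Langerhans cell identity, −1.72 for keratinocyte, −3.32 for neutrophil and −3.68 for erythroid genes. With an estimated correlation the camera calls were lost for cell cycle (adjusted p = 0.478), inflammatory (0.229), immediate early and heat shock (0.0825), keratinocyte (0.0993) and erythroid genes (0.191), and those of the other 5 lists held. With zero groups at the floor the medians were 0.87 for macrophage and monocyte, 0.44 for TGF-β and BMP, 0.31 for cell cycle, −1.22 for inflammatory, −2.90 for neutrophil and −3.97 for erythroid genes, and the other 4 were the same. Of 100 splits of genotype within age, 3 called as many genes as the real split (200 against a highest other of 201). That share speaks only against a grouping with no genotype effect at either age. Splits that mix genotypes also count any real genotype difference as spread, which lowers their calls. Both of the other splits as large kept the 1.5M genotypes whole and mixed those of P5, and the 6 drawn splits of that kind called 122 to 201. The 8 that kept the P5 genotypes whole called 2 to 6, and the 85 that mixed both called 0 in limma. A count near the real one thus needs only the 1.5M difference, so the splits do not show that the effects differ between ages. Exchanging the genotypes at 1 age turns the difference of the knockout effects into their sum, and that split, which was not drawn, called 440.

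Each comparison of 3 libraries against 3 has 10 splits, too few for a share under 0.05. In each, 1 split, the real one, called as many genes, and the highest other called 0. The real counts were 180 for P5 KO against P5 wt, 529 for 1.5M KO against 1.5M wt, 522 for 1.5M wt against P5 wt and 315 for 1.5M KO against P5 KO.

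In P5 KO, Langerhans cell identity genes were lower (adjusted p = 0.0205 with an estimated correlation) while keratinocyte, neutrophil and erythroid genes were higher by camera, 3 calls lost with an estimated correlation (adjusted p = 0.0685, 0.0676 and 0.0959). Dilution of the sorted cells by RNA of other cells would lower their genes alike, and with zero groups at the floor and without any 1 library the Langerhans cell identity median was −0.76 to −0.46, which overlapped MHC class II genes at −0.48 to −0.31. MHC class I (−0.29 to −0.15), lysosome (−0.01 to 0.16) and macrophage and monocyte genes (0.51 to 1.24; adjusted p = 0.0865 with an estimated correlation) lay above that range, but other cells may carry these too, so dilution and a knockout effect cannot be told apart for this list. RNA of other cells in these tubes may account for the other markers, since the lowest coefficient of variation of those 3 summed lists was 66.9%, against 48.2% for cell cycle genes, the highest of 19 tested lists that name no other cell type, and 30.4% for inflammatory genes, the next, although the gate would remove these cell types. The erythroid sum was 401, 521 and 1.19 in the 3 libraries, and a knockout effect on the cells that passed the gate stays open and untested.

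At 1.5M, more genes were detected in KO than in wt, more were called higher than lower, and macrophage and monocyte genes were higher. Over 20 draws thinned to equal depth, the difference in genes detected fell from 1615 to a mean of 345, so deeper libraries may account for most of it. The percent of called genes that were higher went from 61.4 to no lower than 58.1, and the macrophage and monocyte median from 2.23 to no lower than 1.85. Depth was therefore argued against as the whole cause of these 2 patterns, and a knockout effect is a hypothesis that stays open. The gate takes Langerhans cells and related myeloid cells, and each library pools the sorted cells. These values therefore cannot tell a change of expression within cells from a different mix of such cells, which was not tested.

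The P5 wt libraries held few Y-linked transcripts (0.562) and more Xist (25.1 ± 10.6) than the 1.5M wt libraries (3.70 and 9.69 ± 3.46), so the age change in wild type could reflect a different sex mix. The Y-linked sums come from 0 to 7 molecules per library, so the sex mix itself is uncertain. P5 KO libraries carry Y-linked transcripts (4.44) and less Xist than P5 wt (11.1 ± 2.06). Against them the genes called in wild type kept 87.8% of their median difference where higher at 1.5M and 78.8% where lower. A sex mix as the whole cause was argued against by these values. The test shares the 1.5M wt libraries with the selection of genes, and P5 KO differs from P5 wt by genotype, so part of the change may still follow sex. Age stays the open alternative. P5 KO and P5 wt may differ in sex mix too, which was not tested for the knockout effect.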

How the results depend on the processing

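Values by voom, after thinning, without Rn45s and for lists after median-of-ratios scaling or thinning were chosen after seeing the data, as was the count without genes of other cell types. Of 6162 values of 330 named results under alternatives, 5482 kept direction and side of the threshold, 637 lost the call, 16 gained one and 27 reversed. Depth limits low genes most, and thinning cost the call of 78 of 324 named results.

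Genes called in P5 KO against P5 wt went from 180 to 118 with no filter, 92 with a pseudocount of 0.1, 0 in limma on the 6 libraries alone (836 at an unadjusted p under 0.05) and 118 after thinning, with 72 to 123 when 1 library was left out. In 1.5M KO against 1.5M wt, 529 became 865 by voom and 348 after thinning. With age in wild type, 522 became 111 on the 6 libraries alone, 305 after thinning, and 346 to 389 with 1 library left out. With age in KO, 315 became 86 on the 6 libraries alone, 910 by voom, 190 after thinning, and 169 to 246 with 1 library left out. The difference between knockout effects went from 200 to 133 with a pseudocount of 0.1, 348 by voom and 105 after thinning. Leaving out a library leaves fewer samples, and thinning leaves fewer molecules. On its 6 libraries alone 1.5M KO against 1.5M wt gave 630, of which 370 were among the 529. For that and the other settings the cause was not tested.

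With an estimated correlation the called lists fell from 12 to 3 in P5 KO, from 14 to 7 in 1.5M KO, from 11 to 3 with age in wild type, from 11 to 3 with age in KO and from 10 to 5 for the difference. The cause was not tested. With age in KO, 7 to 12 lists were called with 1 library left out. The correlation of age changes between genotypes, 0.186, was 0.218 over genes with a mean above the median and 0.163 to 0.186 with 1 library left out, and the cause was not tested.

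The reversed values were log2 fold changes of genes not called, except Cd207 in the difference between knockout effects (−2.02, but 0.49 with a pseudocount of 0.1, adjusted p = 0.823). At P5, Runx3 was 0.048 by median-of-ratios scaling, 0.017 by voom and −0.32 to 0.19 with 1 library left out, and Tgfbr2 was −0.10 to 0.86. With age in wild type, Runx1 was −0.14 after thinning and −0.019 to 0.94 with 1 library left out. Itgam was 0.023 by median-of-ratios scaling, 0.033 by quantile normalization and −0.50 to 0.37. With age in KO, Runx1 was −0.045 after thinning. In the difference, Runx1 was 0.13 with a pseudocount of 10, 0.10 after thinning and −0.55 to 0.42 with 1 library left out, Cdh1 was −0.11 to 0.86, Itgam −0.19 to 0.68, and Cd74 was 0.22 by quantile normalization. The cause was not tested.

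With the replicate number as a block the counts were 147, 508, 504, 315 and 195, in the order of the comparisons above, and 7 of 330 named results lost the call. Over 18 same-numbered pairs the correlation of deviations was −0.035 to 0.083, so the numbers were not taken to pair the libraries. Scaling to the same total moved nothing, since totals were equal as deposited. A fit of the compared groups alone gives no value for the difference, which uses all 4 groups, and no spike-in scaling was run.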

Other observations

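The comparison of 1.5M KO with P5 wt, its list tests and the medians of genes called in either genotype were chosen after the result was seen.

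Some genes rose with age in both genotypes. H2-M2, a nonclassical MHC class I gene (chromosome 17, 37480851 to 37483552), averaged 0.71 ± 1.23 in P5 wt and 36.8 ± 2.66 in 1.5M wt (log2 fold change 4.69, SE 0.43, adjusted p = 1.72e-07 by limma, n = 3 each). It averaged 0.48 ± 0.84 in P5 KO and 15.8 ± 0.94 in 1.5M KO (adjusted p = 1.22e-05). The tetraspanin gene Cd9 rose from 22.9 ± 2.4 to 58.7 ± 5.96 in wild type and from 19.9 ± 3.1 to 48.6 ± 5.13 in KO. Other genes rose with age in KO and stood near 0 in the other groups. Mmp13, a collagenase, averaged 13.1 ± 1.99 in 1.5M KO and 0 in both wild-type groups, and Dnase1l3, a secreted nuclease, 10.8 ± 1.52 against 0 in P5 KO, at least 12-fold higher. Ptgs1, which encodes cyclooxygenase 1, fell in 1.5M KO from 33.4 ± 10.3 to 0.16 ± 0.28 (adjusted p = 7.31e-10), and Cxcr4, a chemokine receptor, was at least 47.1-fold higher there than in 1.5M wt.

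Genes called with age in wild type had median log2 fold changes of 1.85 (higher) and −1.74 (lower) there and of 0.32 and −0.11 in KO. Genes called with age in KO had medians of 1.75 and −1.89 there and of 0.03 and −0.63 in wild type, so the smaller medians of the other genotype go with the selection and do not show that KO cells change less. Over all 10023 genes the SD of the log2 fold changes was 0.73 in wild type and 0.68 in KO. Separately, the hypothesis that 1.5M KO cells may keep the P5 wt state was tested on the macrophage and monocyte, Langerhans cell identity and lysosome lists, none of which would then be called between 1.5M KO and P5 wt with an estimated correlation. The lowest of the 3 adjusted p-values was 0.0179 by camera, for macrophage and monocyte genes, of which 10 of 25 were higher and 1 lower in 1.5M KO (median 1.02). Langerhans cell identity genes, 1 higher and 5 lower of 11, and lysosome genes, 1 higher of 27 (median 0.21), were called by camera at the preset correlation (adjusted p = 0.0116 and 0.0367), and both calls were lost with an estimated one (adjusted p = 0.0523 and 0.139 with an estimated correlation). In limma, 217 genes were higher and 110 lower in 1.5M KO than in P5 wt. These groups differ in age, genotype and depth, so that count does not decide the question. The macrophage and monocyte list argues only against a state identical to that of P5 wt. How close the 1.5M KO cells stay to that state was not tested.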
